A study of Sus scrofa with 22 samples.

How the data were processed

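Small-intestinal RNA of 22 piglets was measured on 22 two-colour Agilent pig arrays on 7 slides scanned on 3 days. Per the labels, each piglet's RNA was labelled with Cy5 and a pool of all samples with Cy3, with no array in the other dye order, so a dye effect of a probe is common to the arrays and cancels within comparisons. The piglets fall into 4 groups by the labels: DOX treated (n = 6), untreated piglets of the DOX experiment (n = 6), BUCY treated (n = 5) and untreated piglets of the BUCY experiment (n = 5). The replicate is the piglet throughout. Replicate numbers follow the order of the arrays and pair no piglets. The part of the small intestine, the time of sampling, litter, diet and doses are not given in the sources used here. The labels call the piglets 3 days old and do not say whether this is the age at treatment or at sampling.

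The deposited scanner files give median spot and local background intensity in both colours, per the file headers from Agilent Feature Extraction 10.7.3.1. They hold no mean spot signal, so median signals were used in place of the mean signals planned. Per the file headers they also hold a log10 ratio of the processed Cy5 and Cy3 signals, and other columns with quality flags of 0 or 1. The value table deposited by the authors holds log2 ratios of Cy5 to Cy3; the labels name Agilent Feature Extraction and limma, and the normalisation steps are not given in the sources used here. Across 43603 probes each array of that table was checked against normexp-corrected, loess- and quantile-normalised median signals, with r from 0.999 to 1.00 and slopes from 0.994 to 1.01. The table was used only as an alternative.

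Median signals were background-corrected by normexp with an offset of 50 and normalised within each array by loess, control spots at weight 0, with limma 3.58.1 in R 4.3.3. Spots that the scanner software marked as outliers, 3 to 52 per array and touching 91 tested genes, were dropped, and spots of a probe were averaged; 0 spots were saturated. Probe accessions were joined to the RefSeq genes of the pig genome (Sscrofa11.1). Of 43603 probes, 6700 (15.4%) received a gene symbol, 3029 symbols in all, and the others keep the array's own identifier. Each symbol or identifier was represented by its brightest probe and was tested if its Cy5 signal was well above background on at least 5 arrays, which left 24760, of which 2652 had a symbol; for brevity all are called genes. Families of close sequence, such as the MHC and CYP3A genes, can share signal between probes.

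One limma model (lmFit, eBayes, two-sided) with the 4 group means, 18 residual and 3.38 prior degrees of freedom gave 4 comparisons: the DOX effect, the BUCY effect, the difference between these effects, and untreated piglets of the BUCY experiment minus those of the DOX experiment. P-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. SFTPD and DMBT1, named in the study's title, were also tested by exact permutation of the groups. Gene lists for intestinal cell types, immune processes, stress responses and metabolism, 31 in number, were drawn up from general knowledge. The 27 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, a rotation test that does not compare a list with other genes. Missing values were filled with the group mean for these tests only. DOX and BUCY effects were correlated across genes and set against 100 permutations of treatment within the experiments. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

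The comparisons, the gene lists, the alternatives except those said to be added, and the rule for naming genes were fixed before the data were examined. The rule names SFTPD and DMBT1. For each drug it adds up to 6 of the strongest increases and decreases with a symbol and with Cy5 well above background on most arrays of both groups. It also takes 3 genes of each list past the threshold, or with at least 3 such genes, by smallest p, and the top gene of the other lists where that gene passed. For the remaining comparisons it names up to 4 genes in each direction. Genes named outside the rule are said to have been chosen after their values were seen. Where a probe was not well above background on any array of a group, its fold change is given as a bound.

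Alternatives changed the background correction, the normalisation between and within arrays, the use of the Cy3 channel, the filter on dim probes, the choice of probe, the slide as a fixed or random block, the 6 arrays whose title carries a suffix, the samples in the fit, the test, and each array left out. Scan day as a block, the removal of BUCY treated arrays 2 and 3, and camera on the last 2 comparisons were added after the data were seen. Slide 4 holds only BUCY treated array 2, so slide as a fixed block also takes that array out of the comparisons. Within a slide the BUCY effect rests on 1 untreated and 1 or 2 treated piglets. Quantile normalisation of average intensity leaves the ratios as they are, so that alternative tests nothing.

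Signal sets the limit on single probes. Median Cy5 signals were 88 to 210 per array and median Cy3 signals 76 to 132.5; 59.6% to 72.5% of probes were well above background in Cy5 and 66.0% to 79.7% in Cy3. The number of arrays limits the precision of each comparison. The method was tested on simulated data of 24760 genes with 200 changes planted per comparison. It recovered 49.3% of planted log2 changes of 0.5, 88.1% of 1 and 98.5% of 2 for the DOX effect, with 8 false calls. For the BUCY effect it recovered 47.8%, 85.1% and 98.5% with 16 false calls, for the difference between effects 11.9%, 76.1% and 98.5% with 7, and for the untreated piglets 50.7%, 91.0% and 100% with 9. A planted list was recovered in each comparison with 0 other lists called. The simulated noise was independent between genes and arrays, with the same spread in every group. It therefore does not test list calls where genes are correlated. Nor does it test false calls under unequal spread: the median gene SD was 0.243 in BUCY treated piglets and 0.165 to 0.189 in the other groups. Some genes that the naming rule gave are not reported here.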

Results

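Gene expression was measured in the small intestine of 22 crossbred piglets, from 2 separate experiments on damage to the gut by chemotherapy. In one, 6 piglets received a single dose of doxorubicin (DOX), which blocks topoisomerase II, and 6 were untreated. In the other, 5 received busulfan with cyclophosphamide (BUCY), which alkylate DNA, and 5 were untreated. Each value is the log2 ratio of a piglet's RNA to a pool of all samples on the same array. Between 59.6% and 72.5% of probes on an array stood well above background, and the number of arrays limits the precision. Genes were called when limma's adjusted p was under 0.05. The study's title names SFTPD and DMBT1 with the immune genes of the intestine, so neither gene is an independent choice.

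The DOX comparison asks how the intestine of piglets responded to this drug. REG3G, a secreted lectin that kills Gram-positive bacteria, was 5.12-fold higher after DOX (log2 change 2.35, SE 0.423, adjusted p = 0.00588, n = 6 and 6). CD163, a scavenger receptor of macrophages, rose 2.48-fold (adjusted p = 5.06e-04) and CD14, a co-receptor for bacterial lipopolysaccharide, 2.40-fold (adjusted p = 0.00118). Of 21 T and NK cell genes 3 fell past the threshold, among them CD8A, 2.01-fold lower, and LCK, the kinase of the T cell receptor, 1.92-fold lower. The call of that list ended with an estimated correlation (adjusted p = 0.224). CCR10, a chemokine receptor of lymphocytes that home to mucosa, fell 2.20-fold (adjusted p = 5.93e-05).

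SFTPD, surfactant protein D, a secreted lectin that binds microbial sugars, and DMBT1, a mucosal glycoprotein that binds it, were measured in the same samples. SFTPD was 2.10-fold higher after DOX, at 0.68 ± 0.17 (SD, n = 6) against -0.39 ± 0.68 (SD, n = 6) in untreated piglets, and the groups did not overlap. The exact permutation test gave p = 0.00216, the smallest that its 924 splits allow, but SFTPD missed the threshold over all genes (log2 change 1.07, SE 0.287, limma adjusted p = 0.0792). DMBT1 was 1.59-fold higher, at 0.61 ± 0.29 (SD, n = 6) against -0.06 ± 0.22 (SD, n = 6), above the untreated mean in 6 of 6 piglets (exact permutation p = 0.00433, two-sided; limma log2 change 0.67, SE 0.205, adjusted p = 0.124). Adjusted over the 4 exact tests of both genes in both experiments, each p was 0.00794. Within the 3 slides that hold both groups, the SFTPD difference was 1.07 to 2.09 and the DMBT1 difference 0.28 to 0.70; within 2 scan days they were 1.05 and 1.10, and 0.47 and 0.68. With slide as a block SFTPD passed (log2 change 1.39, adjusted p = 0.0121) and DMBT1 did not (0.83, adjusted p = 0.109); with scan day as a block neither did (1.07, adjusted p = 0.0982, and 0.71, adjusted p = 0.123).

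**Figure D1:**
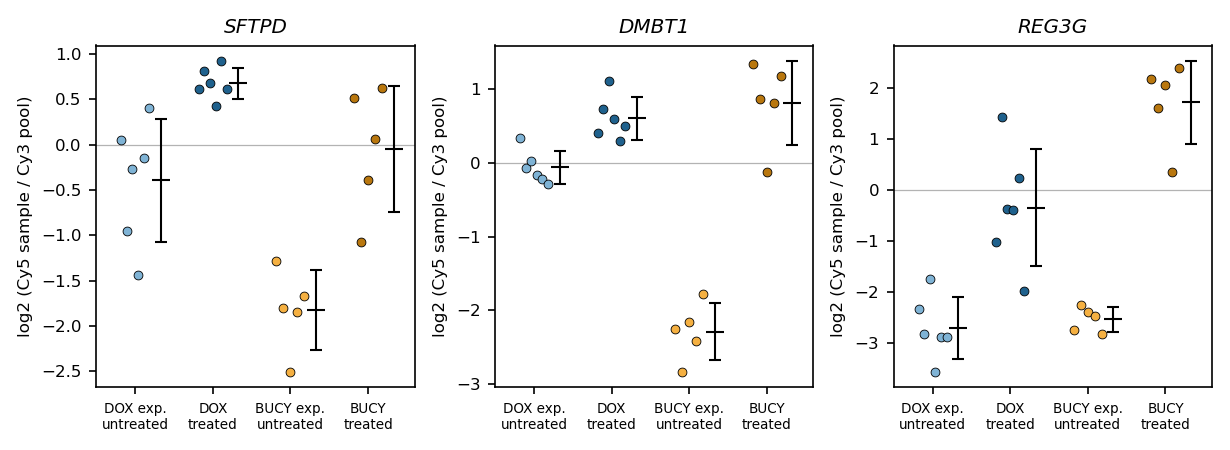
Log2 ratio to the pool (vertical axis) of SFTPD, DMBT1 and REG3G in each piglet of the 4 groups; bars give the group mean and SD. DMBT1 lies at 0.81 ± 0.57 (SD, n = 5) after BUCY and at -2.29 ± 0.39 (SD, n = 5) in the untreated piglets of that experiment.

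Among the strongest increases after DOX were also FMO1, a drug-oxidising monooxygenase, at 3.96-fold (log2 change 1.99, SE 0.265, adjusted p = 1.74e-04), the antimicrobial ribonuclease ANG at 2.45-fold (adjusted p = 0.0108) and the membrane mucin MUC20 at 2.38-fold (adjusted p = 4.23e-04). RETN, the hormone resistin, fell 3.44-fold (log2 change -1.78, SE 0.344, adjusted p = 0.0108). The mitochondrial chaperonin HSPD1 fell 2.10-fold (adjusted p = 0.00859), the mast cell tryptase MCT7 2.07-fold (adjusted p = 0.0309) and SLC10A2, the bile acid transporter of the ileum, 2.05-fold (adjusted p = 0.0219). These genes and REG3G, CD163, CD14, CCR10 and CD8A, 12 in all, lay beyond the untreated mean in 6 of 6 treated piglets. MCT7 missed the threshold when treated array 1, 2, 3 or 6 or untreated array 1, 5 or 6 was left out (adjusted p = 0.0699 to 0.0984). SLC10A2 missed it without treated array 3 or 6 or untreated array 2 or 6 (adjusted p = 0.0520 to 0.0720) and with slide as a block (-0.86, adjusted p = 0.10). Median centring in place of loess ended the calls of REG3G (2.26, adjusted p = 0.0526), CD163 (1.17, adjusted p = 0.159), ANG (1.17, adjusted p = 0.165), MUC20 (1.13, adjusted p = 0.0767), HSPD1 (-1.28, adjusted p = 0.196) and CCNG1 (0.51, adjusted p = 0.579).

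Lists of T and NK cells, mast cells and the cell cycle were lower after DOX at the preset correlation, and their calls ended with an estimated one. Of 21 tested T and NK cell genes, 20 were lower, 3 past the threshold over all genes and 13 lower and 1 higher adjusted over the list alone (median log2 change -0.42, camera adjusted p = 1.73e-09; adjusted p = 0.224 with an estimated correlation). They are CD8A (log2 change -1.0, adjusted p = 2.95e-04), LCK (-0.94, adjusted p = 0.00885) and CD3E (-0.71, adjusted p = 0.0383). CD3E missed the threshold without treated array 1, 2, 3 or 6 or untreated array 1, 2, 3, 5 or 6 (adjusted p = 0.0635 to 0.111) and with scan day as a block (adjusted p = 0.0528). The list median was -0.96 to -0.17 within slides and -0.60 with slide as a block. All 5 tested mast cell and eosinophil genes were lower, 2 past the threshold over all genes and 3 adjusted over the list alone (median -0.50, camera adjusted p = 8.79e-04; adjusted p = 0.173 with an estimated correlation). MS4A2, a chain of the high-affinity IgE receptor, fell 1.41-fold (adjusted p = 0.00601), and CCR3, the eotaxin receptor of eosinophils, was at least 1.78-fold lower with adjusted p = 0.0720. The B cell receptor component CD79A fell 1.66-fold (adjusted p = 0.0219), a call that ended without treated array 1, 3 or 6 or untreated array 5 or 6 (adjusted p = 0.0520 to 0.0672). Only 2 B and plasma cell genes were testable, too few for the list test. The cell cycle list was lower as well, 8 of 9 genes, with 0 past the threshold over all genes and 0 adjusted over the list alone (median -0.37, camera adjusted p = 0.00236; adjusted p = 0.555 with an estimated correlation). Its call ended with slide as a block (-0.28, adjusted p = 0.0823). Cyclin B1 (CCNB1) was at -0.61 (adjusted p = 0.185), AURKA at -0.42 (adjusted p = 0.223) and CDC20 at -0.59 (adjusted p = 0.303).

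Lists of mucosal defence, complement, drug metabolism and ribosomal proteins were higher after DOX at the preset correlation, and their calls ended with an estimated one. In the mucosal innate defence list, which holds both title genes and so is not independent evidence of its direction, 16 of 20 genes were higher. REG3G alone passed over all genes, and 6 passed adjusted over the list alone (median 0.51, camera adjusted p = 8.96e-05; adjusted p = 0.173 with an estimated correlation). Lysozyme (LYZ) was 4.59-fold higher without passing (log2 change 2.20, SE 0.614, adjusted p = 0.0927). The complement and acute phase list had 2 of 21 genes past the threshold over all genes and 4 adjusted over the list alone (median 0.13, camera adjusted p = 0.00712; adjusted p = 0.396 with an estimated correlation). They were the copper carrier ceruloplasmin (CP), 1.89-fold higher (adjusted p = 0.00517), and complement factor B (CFB), 2.17-fold higher (adjusted p = 0.0246); C3 was at 0.75 (adjusted p = 0.0533). CFB missed the threshold without treated array 1, 2, 3 or 6 or untreated array 1, 3 or 5 (adjusted p = 0.0517 to 0.0722) and with slide as a block (1.02, adjusted p = 0.0840). The list's call ended when probes had to be above background on all arrays (0.14, adjusted p = 0.0637). The drug metabolism list was higher with 0 genes past the threshold over all genes and 1 adjusted over the list alone (median 0.24, camera adjusted p = 0.00712; adjusted p = 0.668 with an estimated correlation). Its leading genes were SULT1A3 (0.67, adjusted p = 0.0550), CYP2C42 (1.04, adjusted p = 0.181) and CYP3A29 (1.48, adjusted p = 0.246). Of 23 ribosomal protein genes 21 were higher, 0 past the threshold over all genes and 1 adjusted over the list alone (median 0.16, camera adjusted p = 8.96e-05; adjusted p = 0.396 with an estimated correlation), but the median was -0.0045 under median centring (adjusted p = 0.723). That call also ended with Agilent log ratios, the deposited value table and Cy5 alone. RPLP0 was at 0.44 (adjusted p = 0.0880), RPSA at 0.27 (adjusted p = 0.179) and RPS3 at 0.26 (adjusted p = 0.186).

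The other 20 lists gave adjusted p of 0.0898 or more. In them CCNG1, a p53 target, rose 1.58-fold after DOX (adjusted p = 0.00342) and the collagen gene COL1A2 fell 1.84-fold (adjusted p = 0.0456). COL1A2 missed the threshold without treated array 1, 2, 3 or 6 or untreated array 1, 2, 3, 4 or 5 (adjusted p = 0.0559 to 0.133) and with scan day as a block (adjusted p = 0.0671). The MHC class II list was at -0.21 with 9 of 9 genes lower (adjusted p = 0.0975) and passed with slide as a block (-0.39, adjusted p = 5.63e-04) and with scan day as a block (-0.24, adjusted p = 0.0421). With an estimated correlation and no block its adjusted p was 0.80, and with fry 0.551. Median, mean and camera differed in sign for the p53, macrophage, smooth muscle, pattern recognition, enteroendocrine, oxidative stress and pancreatic lists, none of them past the threshold. By direction, 91 genes rose and 119 fell after DOX, 210 of 24760, against 3418 at an unadjusted p under 0.05. Of the 210, 47 carry a symbol, 25 rose and 40 fell by over 2-fold. With an estimated correlation 0 lists passed and with fry 3. The count was 118 without DOX treated array 3, 131 without array 1 or 2, 133 without array 6, 129 without untreated array 1 and 355 without treated array 4. It was 349 with slide as a block, 199 with scan day as a block and 89 under median centring. It was 694 with scaling between arrays, 749 with only the 2 groups compared, 1264 with array weights and 134 with Cy5 alone.

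The BUCY comparison asks the same of the combination used before marrow transplantation. REG3G was 19.1-fold higher after BUCY (log2 change 4.25, SE 0.463, adjusted p = 1.81e-05, n = 5 and 5), and DMBT1 8.60-fold and SFTPD 3.41-fold. Of 9 cell cycle genes 8 rose, with BIRC5, a survival and mitotic protein, 3.29-fold higher (list adjusted p = 0.109 with an estimated correlation). Of 21 T and NK cell genes 15 fell, with the chemokine CCL5 4.76-fold lower, as did 8 of 9 MHC class II genes. Of 19 enterocyte genes 10 fell, such as TMPRSS15, the enteropeptidase that activates trypsin, 3.89-fold lower. With an estimated correlation the calls of these lists ended (adjusted p = 0.109, 0.189 and 0.472), and the enterocyte call also ended without treated arrays 2 and 3 (adjusted p = 0.295). AQP10, a water and glycerol channel of the epithelium, fell 12.0-fold, to -2.27 ± 1.63 (SD, n = 5) from 1.32 ± 0.79 (SD, n = 5) untreated (log2 change -3.58, limma adjusted p = 7.62e-04). In the DOX experiment AQP10 lay at -2.18 treated and at -1.95 untreated.

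DMBT1 lay at 0.81 ± 0.57 (SD, n = 5) after BUCY against -2.29 ± 0.39 (SD, n = 5) untreated, without overlap (log2 change 3.11, SE 0.224, limma adjusted p = 9.41e-08). SFTPD lay at -0.05 ± 0.70 (SD, n = 5) against -1.82 ± 0.44 (SD, n = 5), also without overlap (log2 change 1.77, SE 0.315, limma adjusted p = 8.90e-04). For both genes the exact permutation test gave p = 0.00794, the smallest that 252 splits allow. Within 3 slides and 3 scan days DMBT1 differed by 2.77 to 3.51 and 2.77 to 3.52, and SFTPD by 1.68 to 3.02 and 1.59 to 2.29. Each of these slides holds 1 untreated and 1 or 2 treated piglets of this experiment. Scan days 2 and 3 hold the same piglets of it as slides 5 and 7, so the ranges are not separate checks. With slide as a block DMBT1 was at 3.07 (adjusted p = 6.43e-05) and SFTPD at 2.17 (adjusted p = 4.44e-04); with scan day as a block they were at 3.15 (adjusted p = 5.48e-07) and 1.78 (adjusted p = 0.00152). Without the 6 arrays whose title carries a suffix SFTPD missed the threshold (1.59, adjusted p = 0.0685, from 2.98e-04 to 0.0685 over its alternatives).

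**Figure D2:**
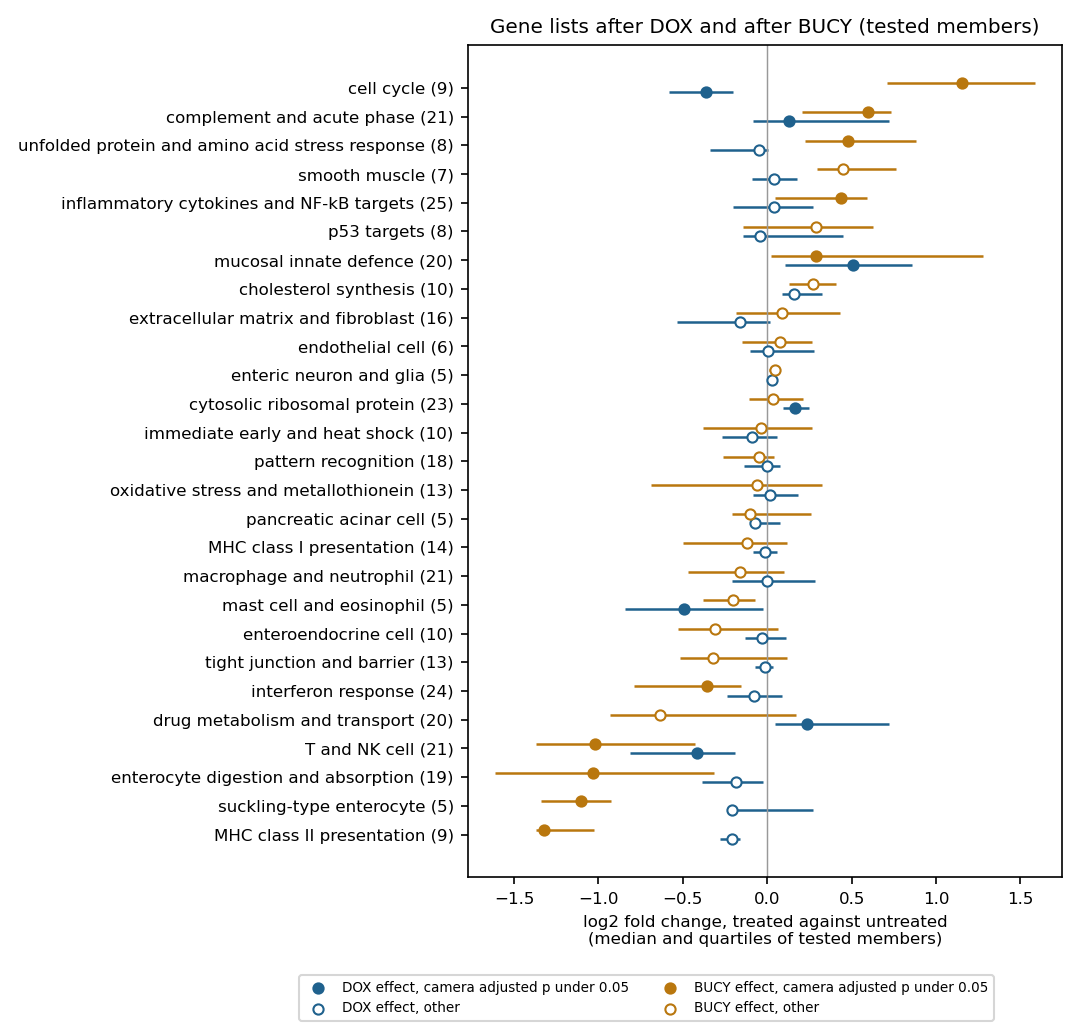
Median log2 change of the tested genes of each of 27 lists (horizontal axis) after DOX and after BUCY, with lines from the lower to the upper quartile; filled points mark a camera adjusted p under 0.05. The T and NK cell list is at -0.42 after DOX and -1.02 after BUCY and the cell cycle list at -0.37 and 1.15; the ribosomal median after DOX turns from 0.16 to -0.0045 under median centring.

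A strong increase after BUCY was also that of SFN, a 14-3-3 protein induced by p53, at 4.95-fold (log2 change 2.31, SE 0.443, adjusted p = 0.00162). The fatty acid carrier FABP3 rose 4.88-fold (adjusted p = 6.53e-05), the desaturase SCD 4.76-fold (adjusted p = 1.81e-05) and the gut glutathione peroxidase GPX2 4.24-fold (adjusted p = 0.00125). Strong decreases were in FOLH1B, 7.79-fold (adjusted p = 1.13e-04), the membrane dipeptidase DPEP1, 6.92-fold (adjusted p = 4.29e-04), the selenium carrier SELENOP, 6.77-fold (adjusted p = 0.00248), the pantetheinase VNN1, 6.46-fold (adjusted p = 5.64e-04), and SDR16C5, 6.00-fold (adjusted p = 0.00822). Each lay beyond the untreated mean in 5 of 5 treated piglets. The adjusted p rest on a spread shared by the 4 groups, but some SDs were wider in treated piglets. They were 1.87 against 0.27 untreated for SELENOP, 1.77 against 0.60 for SDR16C5 and 1.43 against 0.27 for SFN. For FOLH1B and DPEP1 the SDs were somewhat wider in untreated piglets. FOLH1B and DPEP1 lay at 1.58 and 1.53 in untreated piglets here and at -2.29 to -1.27 in the other groups. SFN lay at -2.05 in those untreated piglets and at 0.26 to 0.66 in the other groups. FABP3, SCD and GPX2 lay at -2.46, -2.43 and -1.27 there and at -0.18 to 0.81 in the other groups. Treated arrays 2 and 3 stand apart from all others, at 55.3 and 67.5 on the second principal component, which holds 25.7% of the variance. Array 3 had the lowest median Cy5 signal of all arrays (88, with 59.6% of probes well above background). Array 2 had the lowest of scan day 1 (135, with 66.3%), though some arrays of scan day 3 were dimmer.

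Lists of T and NK cells, MHC class II and interferon response were lower after BUCY at the preset correlation, and their calls ended with an estimated one. In the T and NK cell list 15 of 21 genes fell over all genes and 17 adjusted over the list alone (median -1.02, camera adjusted p = 1.52e-12; adjusted p = 0.109 with an estimated correlation). Examples are CCL5 (log2 change -2.25, adjusted p = 2.83e-05), CD3E (-1.37, adjusted p = 6.24e-05) and CD96 (-1.18, adjusted p = 1.28e-04), lower in 5 of 5 piglets. In the MHC class II list 8 of 9 genes fell, and 8 adjusted over the list alone (median -1.32, camera adjusted p = 6.32e-07; adjusted p = 0.189 with an estimated correlation). SLA-DRA was 3.07-fold, SLA-DQA1 2.58-fold and SLA-DQB1 2.51-fold lower (adjusted p = 7.51e-04, 6.06e-04 and 0.00127), from probes that can share signal between SLA genes. Within slides the T and NK cell median was -0.91 to -0.67 and the MHC class II median -1.11 to -0.54; with slide as a block they were -0.91 and -1.02. The MHC class I list did not pass (-0.12, adjusted p = 0.323), though 3 of its genes fell: B2M, the light chain shared by class I molecules, 2.93-fold (adjusted p = 2.53e-04), SLA-5 2.21-fold (adjusted p = 0.0134) and SLA-3 1.81-fold (adjusted p = 0.0239). In the interferon response list 6 of 24 genes fell, 9 adjusted over the list alone (median -0.36, camera adjusted p = 0.00227; adjusted p = 0.414 with an estimated correlation). The RNA sensor IFIH1 was at -1.46 (adjusted p = 0.00316) and IRF9 at -0.77 (adjusted p = 0.00823). The median was -0.68 to -0.05 within slides and -0.31 with slide as a block.

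The cell cycle list was higher after BUCY at the preset correlation, and its call ended with an estimated one. Of 9, 8 rose over all genes and 8 adjusted over the list alone (median 1.15, camera adjusted p = 3.00e-09; adjusted p = 0.109 with an estimated correlation). BIRC5 was at 1.72 (SE 0.185, adjusted p = 1.81e-05) and CCNB1 at 1.68 (SE 0.233, adjusted p = 1.21e-04), higher in 5 of 5 piglets. BIRC5 lay at -1.57 in untreated piglets of this experiment and at 0.05 to 0.23 in the other groups. CCNB1 lay at -1.84 in those untreated piglets and at -0.16 to 0.57 in the other groups. The list median was 1.2 to 1.26 within slides and 1.25 with slide as a block. SOX9, a transcription factor of crypt cells, rose 1.60-fold (adjusted p = 0.00782). Its list had 4 tested genes, as had the goblet cell list, of which SPINK4 fell 2.17-fold (adjusted p = 0.00300), and no red blood cell gene was tested. Of the p53 targets 4 rose, while the list did not pass (0.29, adjusted p = 0.102). Among the 4 were GDF15 at 4.24-fold (adjusted p = 7.19e-04), FDXR at 1.51-fold (adjusted p = 0.00105) and MDM2, the p53 ubiquitin ligase, at 1.65-fold (adjusted p = 0.00714). GDF15 lay at -1.95 in untreated piglets of this experiment and at -0.02 to 0.73 in the other groups. For FDXR these levels were -0.44 and -0.14 to 0.15, and for MDM2 -0.61 and 0.07 to 0.20.

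Both enterocyte lists were lower after BUCY at the preset correlation, and their calls ended with an estimated one. In the enterocyte list 10 of 19 genes fell over all genes and 11 adjusted over the list alone (median -1.03, camera adjusted p = 3.22e-04; adjusted p = 0.472 with an estimated correlation). TMPRSS15 was at -1.96 (adjusted p = 0.00334), the brush border peptidase DPP4 at -1.67 (adjusted p = 0.00554) and SLC3A1, a subunit of an amino acid transporter, at -1.37 (adjusted p = 0.00584). Without treated arrays 2 and 3 the list median was -0.39 and the call ended (adjusted p = 0.295); within slides it was -1.65 to 0.13, below 0 in 2 of 3, and -0.97 with slide as a block. In the list of suckling-type enterocytes, which take up and digest milk proteins in lysosomes, 4 of 5 genes fell and 5 adjusted over the list alone (median -1.10, camera adjusted p = 4.10e-04; adjusted p = 0.216 with an estimated correlation). The lysosomal enzymes NEU1, GUSB and CTSB were 3.90-fold, 2.53-fold and 2.15-fold lower (adjusted p = 0.00236, 0.00171 and 0.00238). The list median was -1.79 to -1.08 within slides and -1.22 with slide as a block. These 3 genes and LAMP1 are the 4 that fell, and all also stand in the lysosomal list given under other observations. The tested genes therefore cannot tell suckling-type enterocytes from lysosomal genes in general.

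Lists of complement, mucosal defence, inflammation and the unfolded protein response were higher after BUCY at the preset correlation, and their calls ended with an estimated one. In the complement and acute phase list 9 of 21 genes rose and 1 fell, 13 and 1 adjusted over the list alone (median 0.60, camera adjusted p = 9.70e-05; adjusted p = 0.109 with an estimated correlation). The terminal components C9 and C7 rose 3.63-fold and 2.51-fold (adjusted p = 0.00127 and 0.00177) and CFB rose 2.27-fold (adjusted p = 0.00474). In the mucosal innate defence list, which holds both title genes and is not independent evidence, 5 of 20 genes rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone (median 0.29, camera adjusted p = 0.00705; adjusted p = 0.216 with an estimated correlation). PGLYRP2, a peptidoglycan amidase, rose 2.42-fold (adjusted p = 5.38e-04). In the inflammatory list 4 of 25 genes rose, and 4 adjusted over the list alone (median 0.44, camera adjusted p = 0.00817; adjusted p = 0.414 with an estimated correlation). Among them were the neutrophil chemokine CXCL2 at 3.92-fold (adjusted p = 0.00476), IL1B at 2.61-fold (adjusted p = 0.00846) and SELP at 1.76-fold (adjusted p = 0.0167). Without treated arrays 2 and 3 the calls of the mucosal list (median -0.06, adjusted p = 0.0821) and the inflammatory list (0.10, adjusted p = 0.0642) ended. In the unfolded protein response list 4 of 8 genes rose and 1 fell, 5 and 1 adjusted over the list alone (median 0.48, camera adjusted p = 0.0142; adjusted p = 0.216 with an estimated correlation), but the median turned to -0.11 under median centring (adjusted p = 0.614). The chaperones PDIA4 and HSP90B1 rose 1.77-fold and 1.55-fold (adjusted p = 4.13e-04 and 0.0169), and DDIT3, a transcription factor of prolonged stress, fell 1.80-fold (adjusted p = 0.00198). Slide as a block ended the list's call (0.45, adjusted p = 0.0598). Within slides the medians were 0.39 to 0.86 for complement, -0.04 to 0.45 for mucosal defence, -0.05 to 0.44 for inflammation and 0.07 to 0.60 for the unfolded protein response.

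Genes of lists that did not pass also changed after BUCY. The macrophage gene CD163 rose 2.71-fold (adjusted p = 1.67e-04) and CD14 1.75-fold (adjusted p = 0.0138), while AIF1 fell 1.45-fold (adjusted p = 0.0438). CLDN15, a claudin that forms cation pores, fell 3.34-fold (adjusted p = 2.56e-04), CYP2B22 3.78-fold (adjusted p = 2.83e-05) and the pancreatic amylase AMY2 2.35-fold (adjusted p = 4.80e-04). The iron storage genes FTH1 and FTL fell 2.46-fold and 1.61-fold (adjusted p = 0.00134 and 0.00803), the hormone gene GHRL 2.13-fold (adjusted p = 0.00999) and the transcription factor KLF4 1.81-fold (adjusted p = 0.00338). The matrix protease MMP9 rose 2.39-fold (adjusted p = 0.0142), its inhibitor TIMP1 2.04-fold (adjusted p = 0.0172), the muscle filament DES 2.02-fold (adjusted p = 0.0293) and SULT1A3 1.99-fold (adjusted p = 0.00112). RPL27, RPS10 and RPS18 rose 1.35-fold, 1.37-fold and 1.26-fold (adjusted p = 0.00301, 0.00623 and 0.0294), but each was below 0 under median centring, where the median of all genes was shifted by -0.125; the ribosomal list was at 0.03 (adjusted p = 0.380). MS4A2 was at least 1.29-fold lower (adjusted p = 0.0120), with no treated array well above background.

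The naming rule gave further genes for BUCY. PCSK1, which processes peptide hormones, fell 1.48-fold (adjusted p = 0.0102) and the granin CHGB 1.64-fold (adjusted p = 0.0237). The receptors TLR1 and TLR10 fell 1.43-fold and 1.55-fold (adjusted p = 0.00874 and 0.0383), SULT1E1 1.56-fold (adjusted p = 0.0147) and PROX1, with 1 of 3 probes lower, 1.58-fold (adjusted p = 0.00236). The collagenase MMP1 and the neuronal UCHL1 rose 1.69-fold and 1.59-fold (adjusted p = 0.0441 and 0.0257). Without treated array 2 the calls of SLA-5, SLA-3, AIF1, TLR10, TIMP1, MMP1, DES, UCHL1, HSP90B1 and RPS18 ended (adjusted p = 0.0511 to 0.150). Without treated array 3 those of SLA-3, AIF1, CHGB, SELP, TLR10, TIMP1, MMP1, DES, UCHL1 and RPS18 ended (adjusted p = 0.0551 to 0.0987). Calls also ended without untreated array 1 (AIF1, TLR10, MMP1, DES, RPS18), 2 or 3 (these, CHGB, UCHL1) or 4 (MMP1), or without treated array 1 or 4 (AIF1) or 5 (CHGB, MMP1), with adjusted p from 0.0502 to 0.141.

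By direction, 2041 genes rose and 2238 fell after BUCY, 4279 of 24760 (17.3%), against 8000 at an unadjusted p under 0.05. Of the 2041, 929 were called lower and 21 higher in untreated piglets of the BUCY experiment than of the DOX experiment. Independent calls would give 248 and 266. Of the 2238, 1069 were called higher and 101 lower there, against 292 and 272. The comparisons share the BUCY untreated arrays, so the level of those piglets enters both. Of the 4279, 690 carry a symbol, 341 rose and 435 fell by over 2-fold. Of the 27 lists 10 passed, 0 with an estimated correlation and 12 with fry. The count was 2295 with slide and 4304 with scan day as a block. It was 2282 without treated array 2, 2543 without treated array 3, 1125 without both, and 1479 without the 6 suffix arrays. Slide as a block also takes out treated array 2, the only array on slide 4. With only the 2 groups compared in the fit it was 891.

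**Figure D3:**
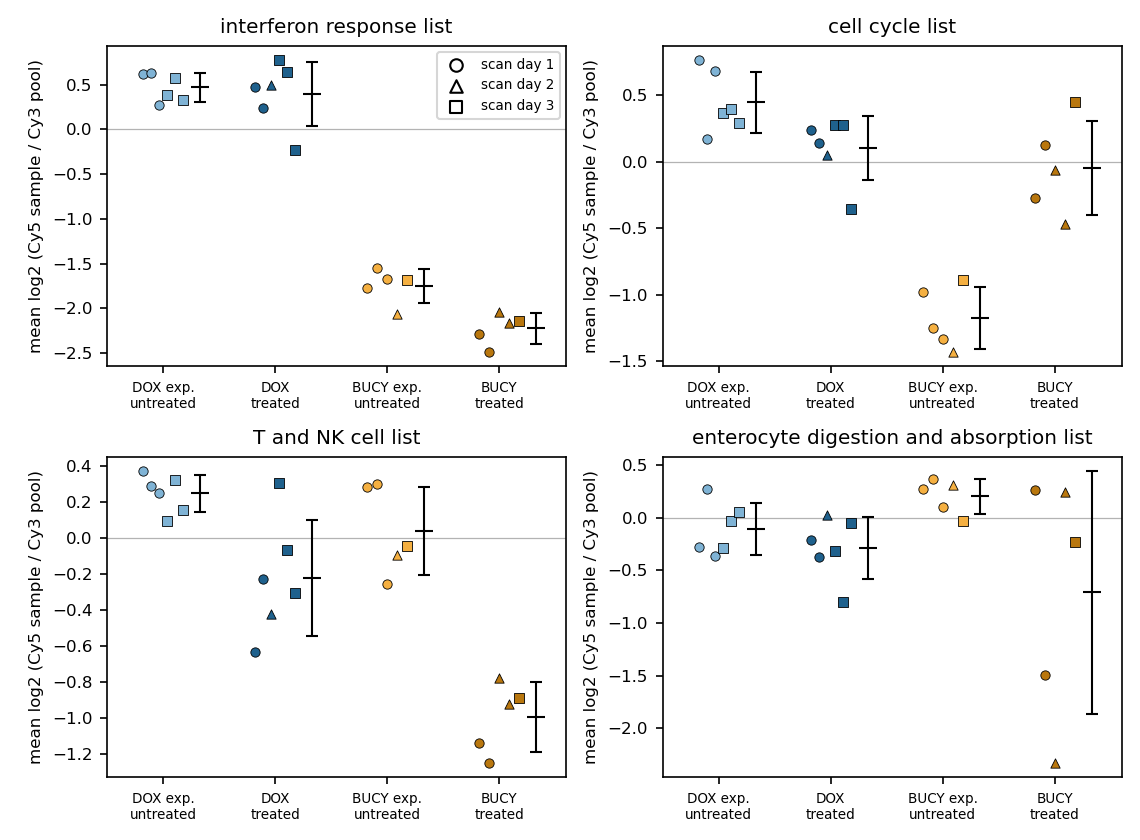
Mean log2 ratio to the pool (vertical axis) of the tested genes of the interferon response, cell cycle, T and NK cell and enterocyte lists in each piglet, with the group mean and SD; symbols give the scan day. The interferon list mean is 0.27 to 0.64 in untreated piglets of the DOX experiment and -2.06 to -1.55 in those of the BUCY experiment.

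Whether a gene responded to the drugs to a different degree was tested by the difference between the effects. DMBT1 rose more after BUCY than after DOX, by 2.44 (SE 0.304, adjusted p = 3.26e-04), while for SFTPD the difference of 0.70 did not pass (adjusted p = 0.397). DMBT1 lay at 0.61 after DOX and 0.81 after BUCY, but at -0.06 and -2.29 in the untreated piglets of those experiments. Its difference thus lies mostly between the untreated groups. In the cell cycle list 8 of 9 genes had a higher change after BUCY over all genes and 9 adjusted over the list alone (median difference 1.40, camera adjusted p = 1.31e-13; adjusted p = 0.0551 with an estimated correlation). CCNB1 differed by 2.29 (SE 0.315, adjusted p = 4.24e-04). It lay at -0.03 after DOX and -0.16 after BUCY, and at 0.57 and -1.84 in the untreated piglets of those experiments. The fatty acid carrier FABP3 differed by 2.47 (SE 0.403, adjusted p = 0.00162) and PHEROC by 3.13 (SE 0.753, adjusted p = 0.0165). FABP3 lay at 0.28 after DOX and -0.18 after BUCY, and at 0.46 and -2.46 untreated. Changes were lower after BUCY for AQP10 (-3.35, adjusted p = 0.0211), SELENOP (-3.32, adjusted p = 0.0123), CYP3A29 (-3.31, adjusted p = 0.0263) and FOLH1B (-2.85, adjusted p = 0.00456).

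Of the other lists, adjusted over all 27, the difference was negative for MHC class II (median -0.98, 3 genes past the threshold, adjusted p = 2.63e-04; adjusted p = 0.502 with an estimated correlation). It was negative for T and NK cells (-0.39, 3 genes, adjusted p = 2.94e-04; adjusted p = 0.526 with an estimated correlation). For suckling-type enterocytes it was -1.38 (2 genes, adjusted p = 0.00205; adjusted p = 0.502 with an estimated correlation) and for drug metabolism -0.85 (3 genes, adjusted p = 0.00496; adjusted p = 0.526 with an estimated correlation). For enterocytes it was -0.95 with 2 genes lower and 1 higher (adjusted p = 0.00835; adjusted p = 0.661 with an estimated correlation). For interferon response it was -0.38 with 0 genes (adjusted p = 0.0257; adjusted p = 0.661 with an estimated correlation). It was positive for the unfolded protein response (0.39, 3 genes higher and 1 lower, adjusted p = 0.00537; adjusted p = 0.333 with an estimated correlation) and for inflammation (0.34, 1 gene higher and 1 lower, adjusted p = 0.0178; adjusted p = 0.526 with an estimated correlation). Adjusted over the list alone, lower changes numbered 5 for MHC class II, 7 for T and NK cells, 3 for suckling-type enterocytes, 8 for drug metabolism and 0 for interferon response. Adjusted over the list alone, 7 enterocyte genes were lower and 1 higher, 4 unfolded protein response genes higher and 1 lower, and 1 inflammatory gene higher and 1 lower. Without BUCY treated array 3 the calls of the enterocyte (-0.57, adjusted p = 0.112), inflammatory (0.25, adjusted p = 0.0531) and drug metabolism lists (-0.73, adjusted p = 0.0531) ended; without treated arrays 2 and 3 the enterocyte difference was -0.24 and camera's direction turned (adjusted p = 0.992). The interferon call ended without BUCY treated array 1 or untreated array 2 or DOX treated array 4 or 5 or untreated array 3 (adjusted p = 0.0570 to 0.0982). CYP3A29 missed the threshold without BUCY treated array 2 (-3.05, adjusted p = 0.0592) or DOX treated array 6 (-3.04, adjusted p = 0.0524). Median, mean and camera differed in sign for the mucosal defence, endothelial, pancreatic and oxidative stress lists, none of them past the threshold. Among 24760 genes the effects differed for 1458, 781 higher and 677 lower after BUCY, against 4885 at an unadjusted p under 0.05. Within scan days 1 and 3 the DMBT1 difference was 3.05 and 2.27 and the cell cycle median 1.52 and 1.66. On day 3, where the BUCY effect rests on 1 treated and 1 untreated piglet and has no spread, other called lists were not seen as on day 1: drug metabolism was at -1.20 and 0.12, interferon response at -0.46 and 0.05 and inflammation at 0.53 and -0.0034. The medians were -1.0 and -0.49 for enterocytes, -1.05 and -1.07 for suckling-type enterocytes, -0.89 and -0.39 for MHC class II, -0.39 and -0.58 for T and NK cells and 0.36 and 0.58 for the unfolded protein response. Slide as a block ended the call of the unfolded protein response (0.37, adjusted p = 0.101), and the complement list, at 0.39, newly passed (adjusted p = 0.010). With scan day as a block the complement list did not pass (adjusted p = 0.0606), and with an estimated correlation and no block its adjusted p was 0.526. With slide as a block DMBT1 was at 2.24 (adjusted p = 0.00349) and the cell cycle list at 1.37 (adjusted p = 3.51e-12). The DMBT1 call ended under median centring (2.0, adjusted p = 0.132), and the count was 104. It was 1078 with slide and 1777 with scan day as a block, 2392 without BUCY treated array 1, 941 without BUCY treated array 2 and 940 without DOX treated array 6. It was 332 without the suffix arrays, 732 without BUCY treated arrays 2 and 3, 747 with Cy5 alone and 2271 with every probe on its own.

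**Figure D4:**
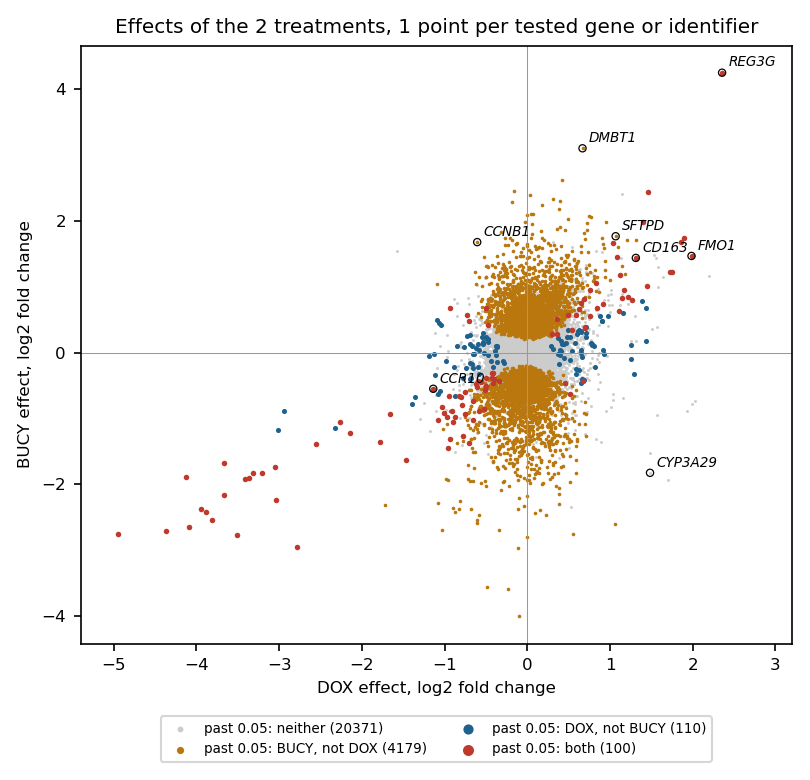
Log2 change after BUCY (vertical axis) against log2 change after DOX (horizontal axis), 1 point per tested gene, coloured by the comparisons in which the adjusted p was under 0.05; 100 genes pass in both.

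Across genes the DOX and BUCY effects had a Pearson r of 0.302 and a Spearman rho of 0.263. Genes are not independent replicates, and 10 of 100 permutations of treatment within the experiments gave an r at least as high and 12 a rho at least as high. Counted in both directions, 20 gave an r and 28 a rho as far from 0, so the permutations do not set the correlation apart from chance. Within scan day 1 the r was 0.457 and the rho 0.439; within day 3, with 1 BUCY treated and 1 untreated piglet, they were 0.0378 and -0.078. Genes called in both comparisons numbered 34 higher in both, 58 lower in both, 3 higher after DOX and lower after BUCY, and 5 the reverse; independent calls would give 7.50, 10.8, 8.23 and 9.81. These overlaps were not set against the permutations. REG3G, CD163, CD14 and CFB rose and CD3E and MS4A2 fell after both drugs. Of the 210 genes called after DOX, 161 (76.7%) had the same sign after BUCY, and 56 of the 210 passed in the test of the difference.

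Untreated piglets of the experiments were compared as the background to the drug effects. Antiviral genes induced by interferon were far lower in untreated piglets of the BUCY experiment, with MX2 17.1-fold lower (log2 difference -4.09, SE 0.236, adjusted p = 5.68e-10). ISG15 was at -3.84 (SE 0.274, adjusted p = 5.11e-09), OASL at -3.83 (SE 0.220, adjusted p = 5.68e-10) and RSAD2 at -3.35 (SE 0.357, adjusted p = 7.69e-07), lower in 5 of 5 piglets. Genes higher there included CYP3A29, 14.5-fold (log2 difference 3.85, SE 0.613, adjusted p = 8.22e-05), FOLH1B (3.75, adjusted p = 5.68e-07), DPEP1 (3.29, adjusted p = 1.08e-05) and AQP10 (3.27, adjusted p = 3.42e-04). Both title genes were lower, DMBT1 at -2.23 (adjusted p = 2.39e-07) and SFTPD at -1.43 (adjusted p = 0.00127). The groups come from separate studies, so the drug comparisons start from different levels.

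In the interferon list 22 of 24 genes were lower over all genes and 23 adjusted over the list alone (median -2.29, camera adjusted p = 3.03e-26; adjusted p = 0.00446 with an estimated correlation). The cell cycle list had 9 of 9 lower, and 9 adjusted over the list alone (median -1.66, camera adjusted p = 4.17e-12; adjusted p = 0.0319 with an estimated correlation). The unfolded protein response list had 5 of 8 lower, and 6 adjusted over the list alone (-0.61, camera adjusted p = 4.31e-05; adjusted p = 0.0319 with an estimated correlation). The calls of the other 6 lists ended with an estimated correlation. MHC class I was at -0.82 (camera adjusted p = 1.23e-07; adjusted p = 0.0515 with an estimated correlation) and inflammation at -0.42 (1.29e-05; adjusted p = 0.109 with an estimated correlation). Macrophages and neutrophils were at -0.27 (1.09e-04; adjusted p = 0.270 with an estimated correlation). Pattern recognition was at -0.27 (2.39e-04; adjusted p = 0.0515 with an estimated correlation), enteroendocrine cells at 0.53 (0.0124; adjusted p = 0.219 with an estimated correlation) and drug metabolism at 0.54 (0.0244; adjusted p = 0.517 with an estimated correlation). Genes lower in these lists over all genes numbered 10 for MHC class I, 10 for inflammation, 8 for macrophages and neutrophils and 8 for pattern recognition, where 1 was higher. Adjusted over the list alone they numbered 11, 12, 8 and 9, with 1 higher for pattern recognition. For enteroendocrine cells 5 were higher and 1 lower, 7 and 1 adjusted over the list alone, and for drug metabolism 7 and 1, 9 and 3 adjusted over the list alone. Median, mean and camera differed in sign for the extracellular matrix, smooth muscle, neuron and ribosomal lists, none of them past the threshold. Over all genes 3228 were higher and 3013 lower, 6241 of 24760 (25.2%), against 8908 at an unadjusted p under 0.05. The interferon median was -2.32 to -2.10 within slides, -2.19 and -2.13 within scan days 1 and 3, and -2.03 with slide as a block. The drug metabolism call ended without BUCY untreated array 1 (0.43, adjusted p = 0.0529) or 4 (0.44, adjusted p = 0.0552) and with slide as a block. The count was 4635 with slide and 6079 with scan day as a block, and 3852 under median centring.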

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

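The tests of leukocytes in the interferon pattern, of a lower share of enterocytes, of each part of the BUCY pattern without treated arrays 2 and 3, and of lists in the untreated piglets and in the difference between effects were chosen only after the results were seen.

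Other splits of the same arrays into groups of the same sizes, 100 per comparison with the real one included, show whether the grouping by chance can be excluded. For DOX 1 of 100 splits gave as many genes, the real one with 210, and the highest other gave 2, so chance is excluded. For BUCY 1 of 100 gave as many, the real one with 4279, but the highest other gave 3979. With another grouping so near the real count, and not every possible split run, these splits do not exclude chance for the BUCY count. That other split put all arrays of the BUCY experiment on slide 5 on one side, and also treated arrays 2 and 3, which stand apart from all others. No test separates these. With slide as a block, which also takes out treated array 2 as the only array on slide 4, the real count was 2295. Without treated arrays 2 and 3 it was 1125. For the difference between effects the splits exchanged treatment in both experiments at once, so they stand for no effect of either drug. They cannot exclude chance for a difference between effects that are not 0. Of 100 splits, 2 reached the real 1458, and the highest other gave 3569. That split set BUCY treated arrays 2 to 5 and untreated array 4 against treated array 1 and the other untreated arrays, with the slide 5 arrays again on one side. It keeps 4 of the 5 treated arrays together against 4 of the 5 untreated ones, with the sides exchanged, so it may restate the BUCY effect, and no test separates this from the slide. With slide as a block the real count was 1078. For the untreated piglets 1 of 100 gave as many, the real one with 6241, and the highest other gave 828, so chance is excluded.

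Interferon response genes were lower in untreated piglets of the BUCY experiment than in those of the DOX experiment, with a median of -2.29 over 24 genes. The values argue against slide or scan day, since the median was -2.19 and -2.13 within scan days 1 and 3, and against single arrays, since the nearest list means of the groups lay 1.82 apart. They also argue against more leukocytes in the DOX experiment's tissue as the whole cause, since the 21 T and NK cell genes, which the intestine itself holds and of which 0 stand in another list, differed by a median of -0.177 with a lower quartile of -0.413 (CD8A at -0.92, CD3E at 0.04 and GZMA at -0.01). The 21 macrophage and neutrophil genes, 4 of them in other lists, went with that explanation, with 18 below 0 and camera adjusted p = 1.09e-04 (adjusted p = 0.270 with an estimated correlation). Their median of -0.268 and lower quartile of -0.643 were still far from the interferon median, and the 2 B and plasma cell genes had a median of -0.54. A part from leukocytes, or from a few in another state, stays open, as does a difference between the studies, which was not tested.

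The BUCY effect ran opposite to the difference between untreated piglets across genes (Pearson r -0.449, Spearman rho -0.337). The comparisons share the BUCY untreated arrays, which alone gave r -0.521 but a covariance of only -0.0143 in simulated data, against -0.0859 observed. With those arrays parted into 2 and 3 so that none served both comparisons, the covariance averaged -0.0704 over 10 splits, and -0.0843 with scan day as a block, which argues against shared arrays and scan day as the whole cause. A response to BUCY and a difference between the studies stay open, untested.

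After BUCY the cell cycle list was higher and the T and NK cell and enterocyte lists lower. A lower share of enterocytes would raise the markers of other cell types alike, while the T and NK cell median was -1.02 with an upper quartile of -0.43. That list was chosen as part of the pattern, so its fall was known beforehand. It therefore cannot test the share of enterocytes, which stays open. With slide as a block 3 of the 3 lists kept direction and call. That block also takes out treated array 2, the only array on slide 4, but keeps treated array 3. Without treated arrays 2 and 3 the number was 2 of 3: the cell cycle and T and NK cell lists passed with adjusted p of 5.73e-13 or less, while the enterocyte list was at -0.39 against -1.03 with them (adjusted p = 0.295). With an estimated correlation and all arrays the calls of the 3 lists ended (adjusted p = 0.109, 0.109 and 0.472). For the enterocyte part the state of those 2 piglets or arrays therefore stays open. For the other part an effect of the drugs stays open, untested, as does a difference of the BUCY experiment's untreated piglets. With slide as a block the cell cycle median was -1.51 in them against untreated piglets of the DOX experiment.

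In 492 groups of arrays, 33 (6.71%) held an array whose gap to its nearest neighbour was large against the group's range by Dixon's test, where chance gives about 1 in 20. DOX treated array 6 held 7 of them: it lay low for CDC20 (0.654 of the range), PDIA4 (0.805), MX2 (0.783), ISG15 (0.633), OASL (0.709) and the cell cycle list mean (0.644), and high for DDIT3 (0.681). Untreated array 4 of the DOX experiment lay high for CCNG1 (0.634), CD96 (0.701) and KLF4 (0.820) and low for CD3E (0.632) and SPINK4 (0.685). Other arrays of the DOX experiment stood apart for CCR10 (0.749, untreated 6), GDF15 (0.882, untreated 2), TLR10 (0.664, untreated 3), DDIT3 (0.635, untreated 5) and DES (0.632, treated 3). BUCY treated arrays stood apart for FMO1 (0.742) and TLR10 (0.818) on array 2, HSPD1 (0.910) and SLC3A1 (0.736) on array 3, DPEP1 (0.824) on array 4 and CD14 (0.773) on array 5. Untreated arrays of the BUCY experiment stood apart for ANG (0.766), RETN (0.735) and CCR3 (0.742) on array 2, SELENOP (0.726), CTSB (0.728) and the MHC class I list mean (0.738) on array 3. They also did for SLA-3 (0.786) on array 4, and CD14 (0.818), FDXR (0.827) and UCHL1 (0.770) on array 5.

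The effects of the drugs differed for 42 named genes and 9 lists in limma's and camera's tests of the difference (BUCY minus DOX, log2). For DMBT1, CCNB1 and FABP3 the treated groups lay closer together than the untreated groups. The difference was positive for PHEROC (3.13), FABP3 (2.47), DMBT1 (2.44), CCNB1 (2.29), GPX2 (2.09), SCD (2.07), BIRC5 (1.90), CDC20 (1.74), HSPD1 (1.52), SLC10A2 (1.46), C7 (1.41), PDIA4 (1.28), SELP (1.14), AURKA (1.13), HSP90B1 (1.12), MDM2 (0.85) and FDXR (0.68). It was negative for AQP10 (-3.35), SELENOP (-3.32), CYP3A29 (-3.31), FOLH1B (-2.85), DPEP1 (-2.79), TMPRSS15 (-2.48), CYP2B22 (-2.19), SLC3A1 (-1.80), AMY2 (-1.69), GUSB (-1.63), ANG (-1.61), FTH1 (-1.42) and CTSB (-1.38). It was also negative for B2M (-1.55), CCL5 (-1.43), SLA-DRA (-1.41), CLDN15 (-1.38), SLA-DQB1 (-1.17), SPINK4 (-1.16), MUC20 (-1.13), SLA-DQA1 (-1.12), CD96 (-0.99), KLF4 (-0.93), DDIT3 (-0.83) and CCNG1 (-0.72). The lists were cell cycle (1.40), unfolded protein response (0.39) and inflammation (0.34) above 0, and suckling-type enterocyte (-1.38), MHC class II (-0.98), enterocyte (-0.95), drug metabolism (-0.85), T and NK cell (-0.39) and interferon response (-0.38) below 0. With an estimated correlation the calls of all 9 lists ended, the lowest adjusted p being 0.0551.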

How the results depend on the processing

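Scan day as a block and the removal of BUCY treated arrays 2 and 3 were chosen after the data were seen; the cause was not tested for any change, except that leaving out arrays also lowers their number. No paired analysis was possible because the replicate numbers pair no piglets. Of the named genes 2192 of 2443 values under other settings and 1390 of 1494 with an array left out kept direction and side of the threshold, and of the lists 619 of 674 and 471 of 481. The other settings include quantile normalisation of average intensity, which leaves the ratios as they are, so its values are kept by construction. In turn 217 and 99 gene values and 54 and 10 list values missed a threshold passed before, and 29 and 4 gene values newly passed. Median centring gave 89 genes for DOX, 104 for the difference between effects and 3852 for the untreated piglets, with RPL27, RPS10 and RPS18 turned to -0.19, -0.19 and -0.33 after BUCY. Scaling between arrays gave 694 genes for DOX, Cy5 alone 134 for DOX and 747 for the difference, and every probe on its own 332 and 2271. Slide as a fixed block gave 349 for DOX and 2295 for BUCY, slide as a random block 355 for DOX, and array weights 1264 for DOX. Fits of only the 2 groups compared gave 749 genes for DOX and 891 for BUCY, so the contrast between the counts depends on which groups are fitted together. Such fits change both the estimate of the spread and the residual degrees of freedom, which were not told apart. Without the suffix arrays the counts were 1479 for BUCY and 332 for the difference. Without BUCY treated arrays 2 and 3 they were 1125 and 732, and the enterocyte difference was -0.24 with camera's direction turned. SFTPD after DOX passed with scaling (1.24), slide as a fixed (1.39) or random block (1.2), 2 groups alone (1.07) and array weights (1.08), with adjusted p from 0.0121 to 0.378 over its alternatives. DMBT1 after DOX passed with 2 groups alone (0.67) and array weights (0.69), from 0.0151 to 0.730. SFTPD after BUCY missed the threshold without the suffix arrays (1.59, adjusted p = 0.0685). With an estimated correlation 0 lists passed for DOX and 0 for BUCY. VPREB1 after BUCY turned to 0.0099 without background subtraction and 0.065 with slide as a block, and was -0.11 to 0.027 with 1 array left out, highest without treated array 1. With 1 array left out the counts were 118 to 355 for DOX, 2282 to 6287 for BUCY, 940 to 2392 for the difference and 5247 to 5871 for the untreated piglets. Lists past the threshold numbered 7 to 9 for DOX and 10 to 12 for BUCY. SFTPD was then 0.86 to 1.23 after DOX and 1.60 to 2.02 after BUCY, DMBT1 0.57 to 0.75 and 2.97 to 3.34, and r between the effects 0.234 to 0.373. Signal over background limits dim probes, since only 59.6% to 72.5% of probes per array were well above it in Cy5.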

Other observations

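The genes and the list in the paragraphs that follow were chosen after their values were seen, and their tests were added then. LOC396781, an immunoglobulin heavy constant gamma gene by its reference synonym, was 17.5-fold lower after DOX (log2 change -4.13, SE 0.362, limma adjusted p = 6.23e-07), at -2.88 ± 0.29 (SD, n = 6) against 1.25 ± 0.78 (SD, n = 6), lower in 13 of 13 probes, which may detect several immunoglobulin genes. After BUCY it was 3.69-fold lower (log2 change -1.88, SE 0.397, adjusted p = 0.00321), and the effects differed by 2.24 (adjusted p = 0.0160). VPREB1, part of the receptor of B cell precursors, fell 2.27-fold after DOX (log2 change -1.18, SE 0.184, adjusted p = 0.00119) and was at -0.05 after BUCY (adjusted p = 0.894). The difference between effects was 1.13 (adjusted p = 0.0162). VPREB1 was well above background on only 2 of 6 DOX treated and 2 of 5 BUCY treated arrays, so its fold changes are limited by dim signal. It lay at 0.58 in untreated piglets of the DOX experiment and at -0.56 in those of the BUCY experiment. The latter is near the -0.60 and -0.61 of the treated groups. A fall after BUCY could therefore hardly be measured, and the difference rests on the starting levels. CCL21, the chemokine that draws lymphocytes to lymphoid tissue, fell after DOX (log2 change -0.97, adjusted p = 0.0376) and BUCY (-0.98, adjusted p = 0.00895). The DOX call of CCL21 ended without treated array 1, 2, 3 or 6 or untreated array 1, 3, 5 or 6 (adjusted p = 0.0666 to 0.0961) and under median centring (-1.07, adjusted p = 0.0688).

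Lysosomal genes were lower after BUCY. A list of 52 lysosomal enzymes and membrane proteins had 23 tested genes. Of these, 4 (NEU1, GUSB, CTSB and LAMP1) also stand in the suckling-type enterocyte list, so the lists are not separate evidence. Of the 23, 15 fell over all genes and 21 were below 0 (median -0.88). Camera gave p = 8.11e-10, and p = 0.0450 with an estimated correlation. These p are unadjusted, unlike those of the other lists. After BUCY smaller such p belonged to the cell cycle, T and NK cell, complement, MHC class II and suckling-type enterocyte lists (0.0092 to 0.0402). Their calls ended after adjustment (adjusted p = 0.109 to 0.216), so 0.0450 is not a call by that standard. After DOX no gene of the lysosomal list passed and its median was 0.12 (camera p = 0.152, and p = 0.622 with an estimated correlation). The difference between effects had a median of -1.01 with 8 genes past the threshold. Camera gave p = 2.38e-11, and p = 0.0308 with an estimated correlation, again unadjusted. For this difference the cell cycle and unfolded protein response lists had smaller unadjusted camera p (0.00204 and 0.0247). Their calls ended after adjustment (adjusted p = 0.0551 and 0.333). In untreated piglets of the BUCY experiment 11 lysosomal genes were higher and 1 lower (median 0.64). Camera gave p = 1.28e-04, and p = 0.196 with an estimated correlation. The granzymes GZMA and GZMB of cytotoxic lymphocytes fell 5.18-fold and 5.11-fold after BUCY (log2 change -2.37 and -2.35, adjusted p = 1.92e-04 and 1.81e-04), lower in 5 of 5 piglets. PLBD1, a phospholipase of phagocytes, was 5.49-fold lower (log2 change -2.46, SE 0.563, adjusted p = 0.00576).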
